A study of Mus musculus with 2 samples.

How the data were processed

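Genomic DNA from 2 regions of the mouse hypothalamus, the paraventricular nucleus (PVH) and the arcuate nucleus (ARH), was compared by methylation-specific amplification microarray. Per the labels, each pool held 7 dissected pieces from C57BL/6 mice of both sexes at postnatal day 10, and 500 ng of DNA went into the assay. DNA is cut first with SmaI, which cleaves the sequence CCCGGG only where its central CpG is unmethylated and leaves blunt ends, and then with XmaI, which cleaves the remaining methylated sites and leaves cohesive ends. Adaptors join the cohesive ends, so PCR enriches fragments methylated at both of their ends. The PVH and ARH products (2 µg of each) were labelled with different dyes and hybridized together. There were 2 arrays, described in the labels as biological replicates. PVH carried Cy5 on replicate 1 and Cy3 on replicate 2, per the labels. The series title and the tissue tag of the second channel name the ventromedial nucleus instead of ARH. Source names, sample titles and the design text name ARH, and that name is used here, with the identity of the second nucleus left open.

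Both scanner files hold linear spot intensities. Per the file headers, the authors extracted them with Agilent Feature Extraction 10.5.1.1 under a CGH protocol, while the submitters' processing notes name version 9.1.3.1. The processed intensity is background-subtracted, spatially detrended and dye-normalized by a single linear factor per channel, per the file headers (the lowess dye factor was 0 in every channel). The deposited LogRatio column is the log10 of red over green, and it equalled the log10 ratio of the processed intensities within 0.001 for 98.65% of spots on replicate 1 and 98.79% on replicate 2. The deposited PValueLogRatio column is a p-value per spot from Feature Extraction's error model and covers error within 1 array. The array design 017202 carries 90526 different probes of 45 to 60 bases in 90535 spots, with positions on mouse build mm8 per the file headers, and 6110 control spots. A deposited table gives log2 values for 23738 intervals of 200 to 2000 bp. Its build and the way probes were combined are not given in the sources used here. Set against the scanner files, its columns followed the mean log2 ratio of PVH over ARH of the probes within each interval, with r = 0.965 and slope 0.966 on replicate 1 and r = 0.980 and slope 0.973 on replicate 2. Scale and direction were settled by this comparison. The medians of the columns were 0.046 and 0.018, and any centring the authors applied stays unknown. Its intervals were taken as the SmaI/XmaI fragments, and 87109 spots lay wholly within one.

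From the scanner files, log2 of PVH over ARH was computed from the processed signals, with the sign of replicate 2 turned for the dye swap. As for ChIP arrays, no loess or quantile normalization was applied, and each array was centred on the median of its tested probes (0.0072 on replicate 1 and 0.0061 on replicate 2 before centring). Control spots, 79 spots flagged as outliers and probes not well above background in at least 1 channel on each array were left out, and 84708 probes remained. No spot was saturated. Probe ratios were averaged per interval, and the 22350 intervals with at least 2 tested probes were tested with limma 3.58.1 (R 4.3.3), using lmFit and eBayes with Benjamini-Hochberg adjustment at 0.05. With 2 arrays and 1 coefficient there was 1 residual degree of freedom per interval. eBayes estimated an infinite prior degree of freedom for intervals, so every interval had the same standard error of 0.26, and very small p-values rest on that estimate. A dye effect of a single fragment stayed in the residual, since a dye term would have left no residual degrees of freedom. Precision is limited by the number of arrays.

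The test was tried on simulated data: 21908 autosomal intervals drawn from the observed differences between arrays, with 200 of them changed. It recovered 11.9% of intervals changed 1.5-fold, 68.7% of those changed 2-fold and 100% of those changed 4-fold. Of its 143 calls, 23 were false, which is above the nominal 5 in 100, and with no change simulated it made 2 calls. The adjusted p-values are therefore optimistic.

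Before the data were examined, the grouping, the tests and the naming rule were fixed: per direction, the 12 genes with the largest absolute mean log2 ratio among regions past the threshold with the same sign on both arrays. With no gene names, the rule was applied to intervals, and its further parts, on members of the gene lists and single genes chosen for these nuclei, could not be applied. Taking the intervals of the deposited table as regions was chosen once that table was seen, as the plan allowed. Gene lists, the position of intervals relative to genes and CpG islands, and all their alternatives were planned but not run. The scanner files and the table name no genes, and the gene table supplied was for GRCm38, whose coordinates cannot be set against mm8 positions. Intervals are therefore identified by mm8 position alone, counted as in the deposited table. Alternatives covered background correction (normexp with an offset of 50 on the median signals, since mean signals were not in the columns), loess, centring, background filters, the deposited table, the eBayes prior, the number and summary of probes, and single arrays.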

Results

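The data were 2 dye-swapped arrays, each setting DNA of a PVH pool against DNA of an ARH pool by the abundance of SmaI/XmaI fragments methylated at both ends. The paraventricular and arcuate nuclei are neighbouring hypothalamic cell groups with roles in feeding and hormone release. The labels conflict on the second nucleus, since the series title and 1 tissue tag give the ventromedial nucleus where the sample names give ARH. It is called ARH here. The comparison asks where DNA methylation differs between them at postnatal day 10. A positive log2 ratio means more signal from PVH. It is read as more fragments with methylated ends, and it is not an absolute methylation level. Effects of dye, of fragment length and of the sex make-up of the pools can also enter the ratio. Between 92.52% and 95.04% of spots were well above background in each of the channels. Median raw signals were 559 to 851, against 39 to 53 on the 1196 negative control spots.

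Of 22350 intervals tested, 311 (1.39%) differed between PVH and ARH at an adjusted p under 0.05 in limma. PVH had the lower signal at 211 of them, with a median fold of 2.10, and the higher signal at 100, with a median fold of 1.99. The ratio went the same way on both arrays for 308 of the 311. It was at least 1.5-fold on both arrays for 284, of which 193 were lower and 91 higher in PVH. The remaining 27 were under 1.5-fold on 1 array, 3 of them with opposite signs on the arrays. In 24 of the 27 the larger ratio was on replicate 1. With the same standard error for every interval, the test was a cut on the mean log2 ratio, at 0.87 in absolute value. Opposite signs needed a far larger ratio on 1 array, so agreement in direction among the 311 was largely set by the selection. It is no separate evidence that the arrays agree, and r over all intervals was 0.088. All 311 lay on autosomes, and 184 differed at least 2-fold on average. At an unadjusted p under 0.05 there were 1382 intervals, against 1118 expected by chance and 1272 when the array signs were left unturned, so that a tissue difference cancels. The unturned count keeps dye effects and includes the 434 X and 8 Y intervals, which mostly shift the same way on both arrays when unturned. It is thus no count of chance alone.

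The intervals with the largest PVH deficit are given by their mm8 positions, since the files pair none of them with a gene. The interval on chromosome 12 at 73856169 to 73856855 had a log2 ratio of -3.45 ± 0.35 (SD, n = 2 arrays), a 10.9-fold lower PVH signal, with all 4 probes above background in both tissues (adjusted p = 6.9e-37, limma). That p rests on the infinite eBayes prior: with about the same ratio it was 1.4e-04 with loess on the processed signals, 1.3e-04 with the length trend removed and 0.0015 with normexp alone, and over all alternatives it ran from 1.7e-40 to 0.0015. Its mean processed signal was 579 in PVH and 6271 in ARH. On chromosome 5, the interval at 119918478 to 119919746 had a measured ratio of -3.41 ± 0.87, but its PVH signal was only 34.4. There, 2 of the 3 probes were not well above background in PVH on at least 1 array, and the ratio was -1.84 with normexp and loess and -1.82 with normexp alone, so its rank among these intervals is not settled. The ARH signal was 365. On chromosome 7, the interval at 131342827 to 131343684 was at -2.75 ± 0.58, with a PVH signal of 478 and an ARH signal of 3204.

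The other intervals of the 12 with the largest PVH deficit had mean log2 ratios from -2.17 to -1.88. On chromosome 13, the interval at 70684118 to 70685080 was at -2.17 ± 0.26 and the one at 52577770 to 52579188 at -2.06 ± 0.29. Chromosome 4 carried a pair of these intervals, at 107178857 to 107179500 (-2.02 ± 0.027) and at 106600781 to 106602099 (-1.88 ± 0.19). So did chromosome 9, at 57994519 to 57994840 (-1.94 ± 0.0049) and at 32293411 to 32294467 (-1.93 ± 0.011). The remaining members were on chromosome 5 at 146901979 to 146902712 (-2.14 ± 0.64), on chromosome 14 at 117114945 to 117115473 (-1.98 ± 0.66) and on chromosome 10 at 82247968 to 82248592 (-1.91 ± 0.39). The adjusted p in limma was at most 3.0e-10 for each of these 12.

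Intervals higher in PVH differed by at most 3.96-fold. The highest was on chromosome 2 at 34804800 to 34805057, with a log2 ratio of 1.99 ± 0.096 (SD, n = 2 arrays), a 3.96-fold higher PVH signal (3820 against 959 in ARH; adjusted p = 2.3e-11, limma). The interval on chromosome 11 at 79587527 to 79588047 was at 1.89 ± 0.71, the one on chromosome 13 at 72423512 to 72424747 at 1.81 ± 0.18 and the one on chromosome 14 at 121618163 to 121619568 at 1.78 ± 0.15. The chromosome 13 interval was dim, with 3 of its 4 probes not well above background in ARH on at least 1 array, and its ratio was 0.65 with normexp and loess and 0.73 with normexp alone. A further interval on chromosome 2, at 172506068 to 172506846, was at 1.75 ± 0.14. Those on chromosome 6 at 33964954 to 33965368 and chromosome 9 at 59937999 to 59939529 were at 1.60 ± 0.12 and 1.52 ± 0.11. Chromosome 7 had intervals at 92571137 to 92571518 (1.44 ± 0.60) and at 70211263 to 70211675 (1.44 ± 0.33). The last of the 12 were on chromosome 13 at 72423077 to 72423511 (1.43 ± 0.13), chromosome 19 at 48120598 to 48121124 (1.36 ± 0.51) and chromosome 11 at 114370480 to 114371450 (1.34 ± 0.16). The adjusted p in limma was at most 5.2e-05 for each of the 12. The intervals on chromosome 6, on chromosome 7 at 70211263 and on chromosome 19 rested on only 2 tested probes each. That is the fewest allowed, and the shared standard error takes no account of it. With normexp background correction and no loess, 8 of these 12 no longer passed (adjusted p from 0.056 to 0.26). The ratio of 7 of the 8 was then still 1.18 to 1.88, including 1.88 on chromosome 11 at 79587527 and 1.36 on chromosome 19 at 48120598, and that of the dim chromosome 13 interval was 0.73.

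**Figure D1:**
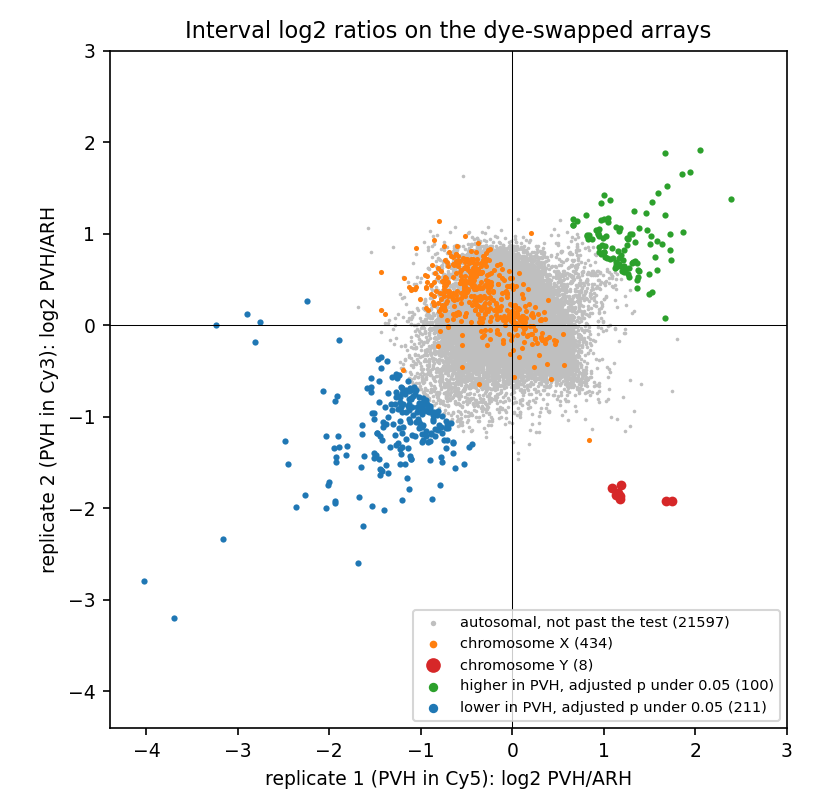
Each point is 1 interval, with the log2 ratio of PVH over ARH on replicate 1 (x axis, PVH in Cy5) and on replicate 2 (y axis, PVH in Cy3). The 211 blue intervals are lower and the 100 green ones higher in PVH at an adjusted p under 0.05; most of the 434 X intervals (orange) lie at upper left and all 8 Y intervals (red) at lower right, where the arrays differ in sign.

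The count of 311 depended on the processing. It was 676 with normexp and loess together, of which 283 were among the 311, 37 with normexp and no loess and 86 with a trend on fragment length removed, all 37 and all 86 among the 311. When the array signs were left unturned, so that the same model measured a dye difference, 2 intervals passed, both on chromosome Y. On simulated data with known changes, 23 of 143 calls were false.

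Differing intervals formed runs. With gaps of up to 100000 bp, 62 of the 311 fell into 27 runs of at least 2 intervals of the same direction, and 6 runs held at least 3. The run with the most intervals was on chromosome 14 from 20771279 to 20783066. Its 3 leftmost intervals (mean log2 ratios of -1.48, -1.45 and -1.65) and 2 rightmost intervals (-1.46 and -1.54) were lower in PVH, with adjusted p of 6.3e-06 or less in limma. The 7 measured intervals between them did not pass, with mean ratios from -0.58 to 0.34. On chromosome 13, all 3 measured intervals from 72423077 to 72426246 were higher in PVH, at 1.43, 1.81 and 1.09, the interval at 1.81 being the dim one that fell to 0.65 and 0.73 under normexp. Other runs of 3 were lower in PVH. They lay on chromosome 9 at 32292320 to 32296138, with a mean log2 ratio of -1.45, on chromosome 8 at 73419127 to 73424606 (-1.41), on chromosome 17 at 85588786 to 85601164 (-1.26) and on chromosome 6 at 88726335 to 88742336 (-0.93). These means cover only the 3 intervals of each run that passed. The chromosome 9 span held 3 measured intervals, those on chromosomes 8 and 17 held 6 each, and that on chromosome 6 held 7. On chromosome 5, both intervals from 119917080 to 119919746 were lower in PVH, the left one at -1.86 and the right one being the interval near background in PVH described above. Touching intervals share a restriction site and are not independent measurements.

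**Figure D2:**
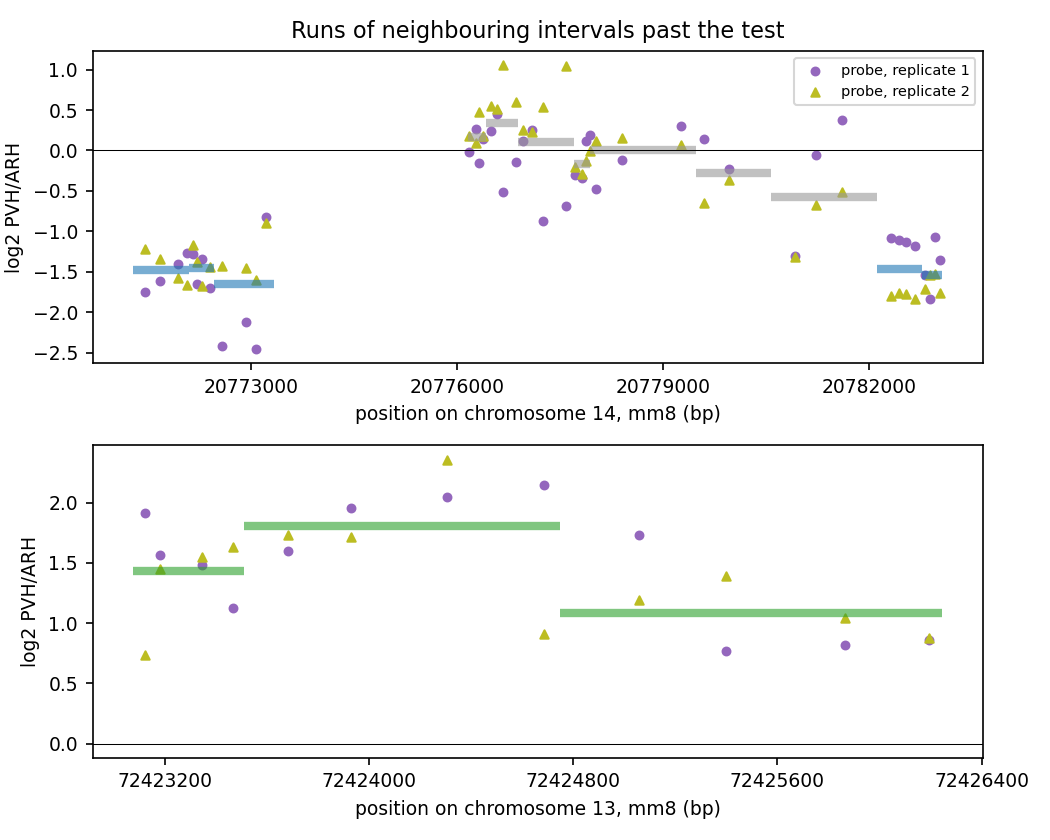
Log2 ratio of PVH over ARH against mm8 position for the runs with the most called intervals lower in PVH (chromosome 14, top) and higher in PVH (chromosome 13, bottom). Symbols are single probes on replicate 1 (circles) and replicate 2 (triangles), and bars are interval means, blue or green where the interval passed the test and grey where it did not. On chromosome 14 the 5 passing intervals flank 7 that stayed between -0.58 and 0.34.

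Of 84708 single probes, 461 passed in limma, 360 lower and 101 higher in PVH, and 400 of the 461 lay in intervals that passed. The count was 892 with normexp and loess, 789 with loess on the processed signals and 198 with a trended robust eBayes prior, with more probes lower than higher in each. At the fixed size of 1.5-fold on both arrays, 1494 probes were lower and 607 higher in PVH, but 1795 reached this size in opposite directions on the 2 arrays, which a difference between the nuclei shared by both replicates would not give. The opposite class was 634 with normexp and loess and 1095 with loess on the processed signals. The excess of lower probes at this size did not hold on each array alone: replicate 1 had 9219 lower and 4943 higher, and replicate 2 had 4635 lower and 6614 higher. At 2-fold the counts were 346 lower, 83 higher and 113 opposite. Among intervals, 79 were at least 2-fold lower, 21 at least 2-fold higher and 13 opposite, of which 5 were autosomal.

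Across all intervals the correlation of the arrays was low and depended on the normalization. Pearson's r was 0.088 and Spearman's rho -0.032 over 22350 intervals, and r was -0.010 and rho -0.11 over 84708 probes. Over intervals, r was 0.29 with normexp and loess and 0.26 with loess on the processed signals. These are across fragments, which are not independent replicates. Agreement varied with signal: r was 0.039 in the dimmest of 8 equal classes and 0.50 in the second brightest. The share of intervals that passed varied with it, from 0.68% in the second dimmest class to 2.33% in the second brightest.

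The sex chromosomes moved in opposite directions on the 2 arrays. The median X probe (1645 probes) was shifted from the autosomal median by a log2 ratio of -0.34 on replicate 1 and of 0.31 on replicate 2. Chromosome Y probes (34) shifted by 1.51 on replicate 1 and by -1.86 on replicate 2. None of 10000 autosomal probe lists of the same size and signal reached any of these 4 medians. For X, the random medians ran from -0.033 to 0.068 on replicate 1 and from -0.059 to 0.014 on replicate 2. The lists were of single probes, while probes of one fragment are amplified together. These random ranges may therefore be too narrow, most of all for Y. All 8 Y intervals were higher in PVH on replicate 1 (1.09 to 1.75) and lower on replicate 2 (-1.92 to -1.74). They have nearly equal lengths in 2 sets, of 560 and 1333 to 1334 bp, and may not be separate sequences. Of 434 X intervals, 344 were below 0 on replicate 1 and 366 above 0 on replicate 2. No X or Y interval passed the test of PVH against ARH. The medians of the 19 autosomes ranged from -0.043 to 0.021 on replicate 1 and from -0.052 to 0.021 on replicate 2.

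**Figure D3:**
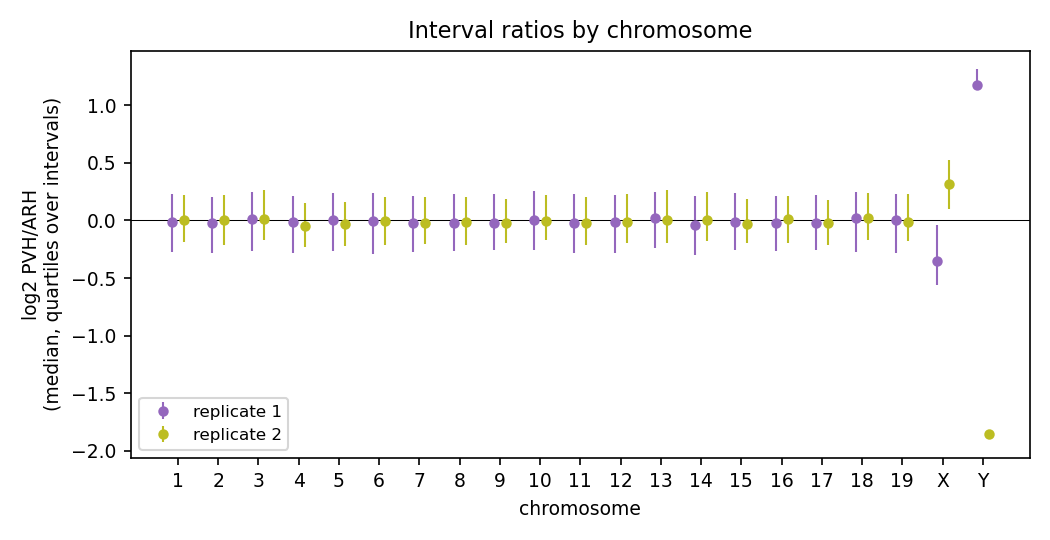
Median log2 ratio of PVH over ARH over the tested intervals of each chromosome (points), with quartiles (bars), on replicates 1 and 2. The 19 autosomes lie within 0.052 of 0 on both arrays, whereas X is at -0.35 and 0.32 and Y at 1.17 and -1.86.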

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

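No further paired analysis was possible, because no block could be added to ratios that already set a PVH pool against an ARH pool on each array. Pairing here means hybridization to the same array only. It does not show that the PVH and ARH pools of an array came from the same animals, so differences between animals may remain. Alternatives named as loess on the processed signals, X and Y left out, a length trend removed and interval calls with unturned signs were chosen after seeing the data. Of 238 alternative results with a test for the 24 named intervals, 229 kept direction and significance, and none reversed. The 9 that did not pass were 8 under normexp with no loess and 1 with the length trend removed. The count of 311 intervals (100 higher, 211 lower) lay between 297 and 380 with no centring, either background filter, loess on the processed signals, the deposited table, X and Y left out, another eBayes prior, at least 3 or 1 probes, or the median over probes. It was 676 (232 higher, 444 lower) with normexp and loess, 37 (4 higher, 33 lower) with normexp alone and 86 (19 higher, 67 lower) with the length trend removed, and 2 with unturned signs. The cause was not tested. The prior degrees of freedom of eBayes were infinite in the chosen fit, with a median SE of 0.26, and 15.97 (SE 0.16), 7.437 (SE 0.19) and 10.46 (SE 0.22) in the first 3 of these, while loess on the processed signals had 8.449 (SE 0.17) and 305 calls. A lost call thus need not mean a smaller ratio: the interval on chromosome 19 at 48120598 was at 1.36 in the chosen fit and at 1.36 with normexp alone (adjusted p = 0.12, limma). In other cases the ratio did fall: the interval on chromosome 7 at 92571137 was at 1.44 in the chosen fit and 1.34 (adjusted p = 0.052, limma) with the length trend removed. That fall need not explain the lost call, since the chromosome 19 interval passed there at 1.28 (adjusted p = 0.049, limma). The share of calls lower in PVH was 67.9% in the chosen fit, 89.2% with normexp alone and 77.9% with the length trend removed.

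Probe calls (461; 101 higher, 360 lower) were 892 (291 and 601) with normexp and loess, 789 (212 and 577) with loess on the processed signals, 198 (33 and 165) with a trended robust prior and 692 at an adjusted p under 0.1 (174 higher). With no background filter, 64 were higher. Feature Extraction's error model gave 2256 (708 higher, 1548 lower) at p under 0.01 on both arrays, beside 2034 in opposite directions. Of probes at least 1.5-fold apart, those opposite on the arrays numbered 634 with normexp and loess and 1095 with loess on the processed signals, and 378 were higher in PVH with normexp alone. At 2-fold there were 83 higher, 346 lower and 113 opposite. On a single array, 4943 to 6614 probes were higher and 4635 to 9219 lower, with more lower on replicate 1 (9219 against 4943) and more higher on replicate 2 (6614 against 4635), and no test of a single array was possible. The r between arrays over intervals was 0.29 with normexp and loess, 0.057 with normexp alone, 0.26 with loess on the processed signals, 0.12 without X and Y, 0.052 with the length trend removed and, by construction, -0.088 with unturned signs. Over probes it was 0.083, -0.076, 0.11 and 0.013 under the first 4 of these. The X shift was -0.29 and 0.27 on replicates 1 and 2 with normexp and loess and -0.27 and 0.25 with normexp alone. Why the processing changed these values was not tested. Leaving out saturated spots removes none, and the deposited table has no values for single probes. The r over intervals was 0.039 in the dimmest of 8 signal classes and 0.28 in the brightest, and 0.087 with only probes well above background in both channels kept, so what signal over background limits was not settled. Gene list and gene location alternatives were not run.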

Other observations

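The comparison of chromosomes and fragment lengths and the tests of explanations for the sex chromosome shifts were chosen only after the results they bear on were seen. So were the other tests for the weak agreement between arrays and the counts of neighbouring intervals by block or without their largest run. The first test of neighbouring intervals was chosen before, as was the test of length effects on that agreement other than an additive trend.

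Differing intervals were spread over all 19 autosomes, from 6 of 716 tested intervals on chromosome 19 (0.84%) to 19 of 709 on chromosome 14 (2.68%). Chromosome 13 had 19 of 774 (2.46%) and chromosome 4 had 22 of 1810, of which 21 were lower in PVH. No chromosome differed from the rest by Fisher's exact test after adjustment over 21 chromosomes (lowest adjusted p = 0.082, for chromosome 14 and for X, with 0 of 434). Fragments of 577 to 775 bp passed in equal numbers in both directions (29 and 29), while among those of 1019 to 1302 bp 43 were lower and 10 higher in PVH. The difference between these length classes was not tested, and the median log2 ratio of all intervals of 1019 to 1302 bp was itself -0.17 on replicate 1 and -0.037 on replicate 2.

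A set of 27 intervals passed although 1 array showed less than a 1.5-fold difference or the opposite sign, and in 24 of them the larger ratio was on replicate 1. Chosen after their values were seen, the interval on chromosome 1 at 47774470 to 47774794 had log2 ratios of -3.23 on replicate 1 and -0.0019 on replicate 2, the one on chromosome 2 at 110724745 to 110725394 had -2.81 and -0.18, the one on chromosome 1 at 49908398 to 49908872 had -2.90 and 0.12, and the one on chromosome 6 at 21525054 to 21525775 had -2.75 and 0.030. Each rests on 4 probes.

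The opposite shifts of X and Y on the 2 arrays are consistent with the hypothesis of pools that held different shares of male tissue, with more male DNA in PVH on replicate 1 and in ARH on replicate 2: all 8 Y intervals had the sign opposite to that of the X median on each array. The labels give both sexes for every pool, and the number of males is not stated in them. In dye terms, the Cy5 channel was lower on X and higher on Y on both arrays. A dye effect particular to these chromosomes, and not tied to intensity, would therefore give the same pattern. These 2 arrays cannot tell it from pool make-up. An intensity-dependent dye effect is argued against, since 0 of the matched autosomal lists, over both arrays, lay as far out as the X probes. Those lists were of single probes, so their spread may be understated. Wrongly labelled dyes on 1 array are argued against as well, because with unturned signs only 2 intervals passed, against 311 with the swap. A sex imbalance that runs in opposite directions on the 2 arrays would not give autosomal ratios of the same sign on both.

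The weak agreement of the arrays over all intervals may come in part from a dye effect that changes with intensity: the median log2 ratio of the brightest class was 0.35 on replicate 1 and -0.28 on replicate 2, and loess on the processed signals raised r over autosomal intervals from 0.12 (jackknife SE over chromosomes 0.013) to 0.31. Removing a trend on fragment length on each array lowered it to 0.084, which argues against an additive length trend as the cause. Part of the agreement may itself follow length, since the dye swap does not cancel a trend shared by both arrays. Over all intervals, median log2 ratios on replicates 1 and 2 were 0.080 and 0.13 at 300 to 419 bp. They were -0.27 and -0.046 at 1303 to 1615 bp, while the classes of 577 to 775 bp and 776 to 1018 bp had opposite signs on the arrays. Other effects of length stay open, since r over 8 length classes of autosomal intervals ran from -0.10 (578 to 777 bp) to 0.34 (1019 to 1301 bp), and after loess the gap between the highest and lowest class was still 0.39. That remaining gap rests on the longest fragments: after loess r was 0.038 at 1615 to 2000 bp and 0.26 to 0.43 in the other 7 classes, including 0.26 and 0.30 in the 2 classes where it had been below 0. Small tissue differences and differences between pools were not tested as causes.

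Called autosomal intervals of the same direction lay close together: among 5015 touching pairs, 21 were both called, all 21 in the same direction, against a mean of 0.56 and at most 5 in 10000 shuffles of the calls within classes of equal signal. A restriction site shared by 2 fragments could couple touching pairs, and this stays open for them. Pairs that do not touch and lie 2000 to 100000 bp apart were called in the same direction 21 times and in opposite directions 4 times, against a mean of 6.57 and at most 18 in the shuffles (permutation p = 1e-04, one-sided, the smallest they can give), and without the run on chromosome 14 in 15 cases against a mean of 6.36 and at most 19 (permutation p = 0.0034), but coupled neighbours enter these counts more than once. With intervals under 2000 bp apart taken as 1 block, 15 pairs of blocks were both called, 11 in the same direction and 4 not, the 11 against a mean of 5.24 and at most 17 in shuffles of blocks of like size and signal (permutation p = 0.021, one-sided), and 10 against 5.14 and at most 16 without the run on chromosome 14 (permutation p = 0.039), which argues, by a small margin, against a shared site as the whole cause. Over all intervals, called or not, replicate 1 of one interval was set against replicate 2 of its neighbour. Here r was 0.17 for touching pairs and 0.0036 for the pairs farther apart. Without loess, r of autosomal intervals with themselves across the arrays was only 0.12. A dye effect that changes with intensity can also lower r, since its sign is opposite on the 2 arrays. The value of 0.0036 therefore does not settle whether coupling over distance is general. Whether the runs mark regions regulated together was not tested.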
